A study of Mus musculus with 6 samples.

How the data were processed

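Single-cell RNA-seq of sorted adipose stromal cells from female C57Bl6/J mice was available for 6 groups, low fat (LF) or high fat (HF) diet with estradiol (E2), E2 plus tamoxifen (E2+TAM) or E2 withdrawal (EWD). Per the labels' protocols, adipose tissue was digested with collagenase, stained for CD45, CD31 and CD29, and CD29+ cells were retrieved for libraries of polyadenylated RNA with a Chromium 3' kit. Each group was 1 library from 2 to 3 pooled mice, so samples were grouped by their titles and no group had replicates. The processed data were 1 deposited table of raw UMI counts per gene and cell (35327 genes and 72634 cells), whose values were whole numbers with cell totals that differed from cell to cell. Per the submitters' processing notes, kallisto 0.46.2, bustools 0.39.4 and Seurat were used with GRCm38, without a stated role or order. The highest mitochondrial share of any cell in the table was 5.00%, so cells above that share had been removed before deposit. Empty-droplet and other filters of the authors are not given in the sources used here.

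Cells were assigned to libraries by the start of their column names. Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which removed 12, and Scrublet, run per library through scanpy 1.11.5 with an expected rate of 6%, called 23 doublets, which were removed. This is 0.0317% of cells, far below the expected rate. Either the caller missed doublets or they had been removed before deposit, which was not tested, so doublets may remain. Leaving out the 6% of cells with the highest doublet score per library was added as an alternative. The 72599 kept cells were log-normalized and clustered on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm (leidenalg 0.10.2) at resolution 0.5, without integration of libraries, which gave 21 clusters. Clusters were named only from 18 marker lists fixed before the data were examined. The stromal class was 13 clusters, with 67748 cells, in which all 8 fixed stromal markers were detected and whose 10 leading genes against clusters of other types held no marker of another type. In 5 of them these 10 genes held no stromal marker either. The rule fixed before the data were examined asked for leading genes of the stromal lists, so the class was wider than that rule. All 8 stromal markers were also detected in the epithelial-like, endothelial-like, mixed and low-UMI clusters, so their detection did not separate the class. The low-UMI clusters met the second criterion as well. Clusters with a median UMI count far below that of their libraries (ratios of 0.281 and 0.163), a limit set after the data were seen, stayed unnamed and out of the class. Because the first clustering separated libraries, class cells were clustered again on 1413 of the variable genes, after 587 genes were left out whose log2 level differed between libraries by at least 0.58 in at least 2 clusters, with 20 components and resolution 0.3, which gave the subtypes. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. Free RNA in droplets was not modelled.

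For tests, raw counts were summed per library over the stromal class. An additive model of diet and treatment over all 6 libraries was fitted with edgeR 4.0.16 (TMM factors, filterByExpr, robust glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over 19426 genes and calls at an adjusted p under 0.05. With 1 library per diet and treatment, its spread is the disagreement between diets or treatments, with 2 residual degrees of freedom. Nothing shows the spread between separate mice. The biological coefficient of variation was 13.4%. A standard error is the absolute log2 fold change divided by the square root of the F statistic. Apart from the departures in forming the class given above, the design was fixed before the data were examined. Its contrasts were diet, withdrawal, tamoxifen and tamoxifen against withdrawal. In tests on data simulated from these libraries, 95%, 94% and 95% of genes changed 2-fold were recovered for diet, withdrawal and tamoxifen, and 70%, 61% and 50% of genes changed 1.5-fold, with 5, 10 and 3 unchanged genes called among 19209, 19251 and 19215. With the E2 and E2+TAM libraries alone, 95% of genes changed 1.5-fold were recovered for both diet and tamoxifen, with 10 and 0 unchanged genes called. Those simulations changed only genes above 5 CPM, so they do not show recovery of genes below that level. They gave each gene the spread of the fitted trend, with no differences in spread between genes around it and no difference between pools of mice. They can therefore overstate recovery in the real counts. A lack of calls for diet or tamoxifen does not show that no gene changed 2-fold.

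Lists of genes (27 pathway and quality lists fixed before the data were examined) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over lists within each contrast. Fry's test asks whether a list's genes move, on balance, one way. Counts of called members are over all genes and, separately, adjusted over the list alone. Markers of other cell types were counted the same way but not tested as lists.

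Genes were named by a rule fixed before the data were examined. For each of diet, withdrawal and tamoxifen it takes the 10 called genes with the largest change in each direction, with a mean of at least 20 CPM and the same sign in every stratum, or, where fewer than 5 were called, the 10 with the smallest p as values only. It adds up to 4 members with the largest change from each list and always a fixed set, of which Esr1, Pgr, Greb1, Fgfr1, Fgf1, Igf1, Dpp4, Pparg and Fabp4 are reported. The values of some genes that the rule takes are not reported here. Values within a diet are the 5 largest in each direction among genes of at least 50 CPM, as log2 ratios of CPM with 0.5 counts added and Poisson intervals. Genes named for tamoxifen against withdrawal, for the subtypes and for the 4 libraries without EWD were chosen from these after their values were seen. Ribosomal protein genes and predicted genes were counted but not named. Coordinates are from the GENCODE annotation of GRCm38, in which 211 of 214 named genes had a single match by symbol. Genes with close paralogs (such as the H2-Q, Akr1c, Klk1b, Olfr and Ifit3 families) are uncertain, since reads can be split between copies.

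Alternatives were RLE size factors, DESeq2 1.42.0 with the same design, no filter on low counts, all kept cells, no filter or a stricter filter on cells, doublets kept, counts thinned to the smallest library, equal weight per cluster, each library left out in turn, designs without the second term, camera with an estimated correlation, fry, another clustering resolution, and other minimum CPM values. Added after the data were seen were the score-based doublet removal, equal weight per subtype, the class without its interferon-led cluster, cells with a mitochondrial share between 0.5% and 1%, each subtype alone except the Uts2 cluster, and the E2 and E2+TAM libraries alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used for the rest.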

Results

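Gene expression was measured in single adipose stromal cells of female C57Bl6/J mice kept on a low fat (LF) or a high fat (HF) diet. Within each diet the mice received estradiol (E2), E2 with tamoxifen (E2+TAM), a selective estrogen receptor modulator, or withdrawal of E2 (EWD). The stromal fraction of digested adipose tissue was sorted for CD29+ cells, with CD45+ leukocytes and CD31+ endothelial cells depleted. Each of the 6 groups was 1 library pooled from 2 to 3 mice, so no group had replicates. The deposited table held 15422, 8579 and 11256 cells for LF E2, LF E2+TAM and LF EWD, and 18034, 8959 and 10384 for HF E2, HF E2+TAM and HF EWD. Their total UMI counts were 178472811, 86260209, 87090257, 183904214, 88766427 and 107126697 in that order, and the median UMI counts per kept cell were 10974, 9916, 7482, 9794, 9531 and 10178. The comparisons ask how adipose stromal cells of lean and obese females respond to loss of E2 and to tamoxifen.

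Stromal cells expressing Pdgfra, Dcn, Lum and collagen genes made up 94.6%, 95.1% and 94.4% of kept cells in the LF E2, LF E2+TAM and LF EWD libraries and 92.7%, 91.0% and 91.8% in the HF libraries in the same order. Within this stromal class, 3 subtypes had fixed stromal markers among their 50 leading genes. Preadipocyte-like cells expressed Fabp4, Cd36, Col4a1 and Col4a2, genes of fatty acid handling and basement membrane. Dpp4 progenitor-like cells expressed Pi16, Sema3c and Limch1, markers of early adipose progenitors. F3 stroma-like cells expressed Clec11a, Gdf10 and Vit. The other subtypes are named by a leading gene, as the Tnc, Cilp and Uts2 clusters. Preadipocyte-like cells held 42.3% of the class in LF E2 (exact Clopper-Pearson 95% interval 41.5 to 43.1), 42.2% in LF E2+TAM (41.1 to 43.3) and 60.8% in LF EWD (59.9 to 61.8). On HF their share was 47.2% with E2 (46.5 to 48.0), 46.4% with E2+TAM (45.3 to 47.5) and 61.3% with EWD (60.4 to 62.3). Dpp4 progenitor-like cells held 31.0% of the class in LF E2, 36.1% in LF E2+TAM and 13.4% in LF EWD, with 25.9%, 25.6% and 21.7% in the HF libraries. The difference in preadipocyte-like share between EWD and E2 was 18.55 percentage points on LF and 14.10 on HF. The Tnc cluster held 18.3% in LF EWD against 16.1% in LF E2, and 8.74% in HF EWD against 16.2% in HF E2, which became 13.2% against 17.4% with the first clustering. The Uts2 cluster held 0.144%, 0.123% and 0.0942% in LF E2, LF E2+TAM and LF EWD and 0.783%, 1.58% and 0.262% in the HF libraries. With the first clustering these shares were 0.0412%, 0.0368% and 0% on LF and 0.801%, 1.64% and 0.399% on HF. These intervals cover counting error only, and with 1 library per group no difference in shares has a replicate check. The sort sets which cells could enter, and clusters of low UMI count, left out of the class by a limit set after seeing the data, held 4.35%, 3.82% and 2.43% of kept cells in the LF libraries and 5.93%, 7.59% and 5.07% in the HF libraries.

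**Figure D1:**
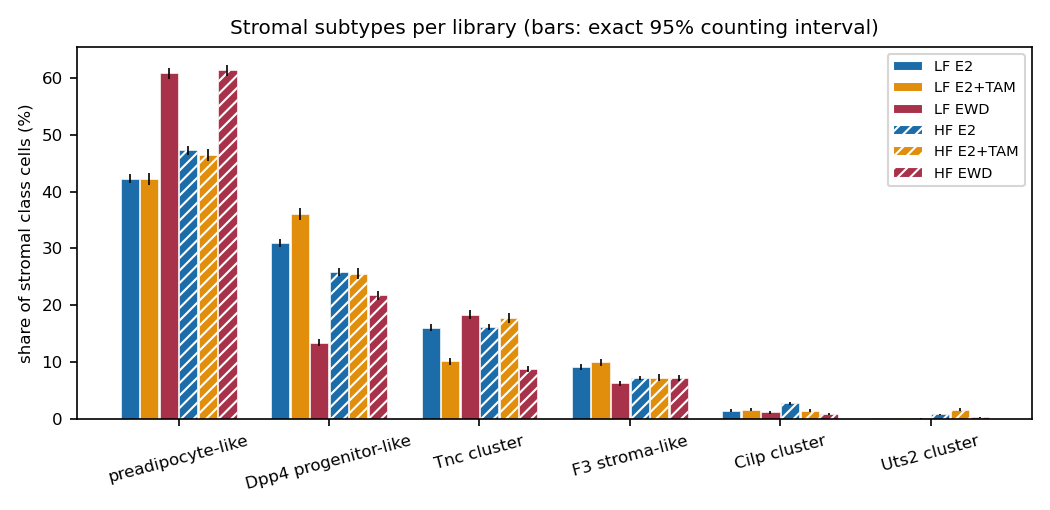
Share of stromal class cells in each subtype (percent, vertical axis) for the 6 libraries, with LF libraries as plain and HF libraries as hatched bars and exact 95% binomial intervals for counting error as error bars. The preadipocyte-like share was 60.8% and 61.3% in the EWD libraries and between 42.2% and 47.2% in the other libraries.

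Withdrawal was compared with continued E2 across both diets on UMI counts summed per library over the stromal class. Pgr, which encodes the progesterone receptor and is a classic target of the estrogen receptor, fell from 53.7 and 42.5 CPM (counts scaled to library size) in the LF and HF E2 libraries to 3.70 and 5.54 CPM in the EWD libraries. Greb1, an estrogen-induced growth regulator, Akr1c14, a hydroxysteroid dehydrogenase, and Spon1 and Spon2, secreted matrix proteins, also fell. Hmcn2, Bgn and Mgp, which encode extracellular matrix proteins, rose together with Gdf15, a stress-induced cytokine gene, and Nr1d1 and Tef, transcription factors of the circadian clock and its output. Of 19426 genes tested, 124 were called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 52 rose and 72 fell. Of the 124, 87 changed more than 2-fold.

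Pgr (chromosome 9, 8899833 to 8968611, GRCm38) changed by -3.36 ± 0.26 (log2, SE of the fit over 6 libraries; adjusted p = 0.0214, edgeR quasi-likelihood test). Greb1 (chromosome 12, 16670615 to 16800886) changed by -2.91 ± 0.23 (adjusted p = 0.0214, edgeR). Akr1c14 (chromosome 13, 4049011 to 4090688) changed by -2.41 ± 0.14 (adjusted p = 0.0130, edgeR), a gene whose reads may be shared with other Akr1c genes of high similarity. Spon2 (chromosome 5, 33198184 to 33218455) and Spon1 (chromosome 7, 113765998 to 114043370) changed by -2.13 ± 0.10 and -1.82 ± 0.10. The other named genes that fell were Krt19, a keratin (-1.86 ± 0.12), Irf7, a transcription factor of the interferon response (-1.85 ± 0.14), Cd320, the cellular receptor for vitamin B12 bound to transcobalamin (-1.57 ± 0.12), Emb, an immunoglobulin superfamily membrane protein (-1.56 ± 0.12), Ampd3, an AMP deaminase (-1.50 ± 0.13), and Cxcl10, an interferon-induced chemokine (-1.40 ± 0.16). Among genes that rose, Hmcn2 (chromosome 2, 31314415 to 31460738) changed by 2.05 ± 0.14 (adjusted p = 0.0155, edgeR), from 13.5 and 21.0 CPM with E2 to 57.6 and 83.2 CPM with EWD on LF and HF. Gdf15 (chromosome 8, 70629393 to 70632456) and Mgp (chromosome 6, 136872435 to 136875823), an inhibitor of calcification, both changed by 1.85 ± 0.18 (adjusted p = 0.0329, edgeR). The remaining named genes rose by 1.79 ± 0.20 for Ndufa4l2, a hypoxia-inducible mitochondrial protein, 1.35 ± 0.15 for Fhl2, a LIM domain cofactor, 1.33 ± 0.12 for Nr1d1, 1.32 ± 0.10 for Cpxm2, 1.28 ± 0.13 for Zbtb16, a glucocorticoid-inducible transcription factor, 1.26 ± 0.12 for Tef and 1.24 ± 0.12 for Bgn, the proteoglycan biglycan. Esr1, the estrogen receptor gene, had a value of 0.58 ± 0.09 and was not called (adjusted p = 0.0758, edgeR). Igf1, an insulin-like growth factor, had 0.70 ± 0.14, the progenitor marker Dpp4 -0.71 ± 0.12, the adipogenic regulator Pparg 0.61 ± 0.17, the lipid chaperone Fabp4 0.40 ± 0.16, the fibroblast growth factor receptor Fgfr1 0.27 ± 0.09 and its ligand Fgf1 -0.15 ± 0.30, none of them called.

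**Figure D2:**
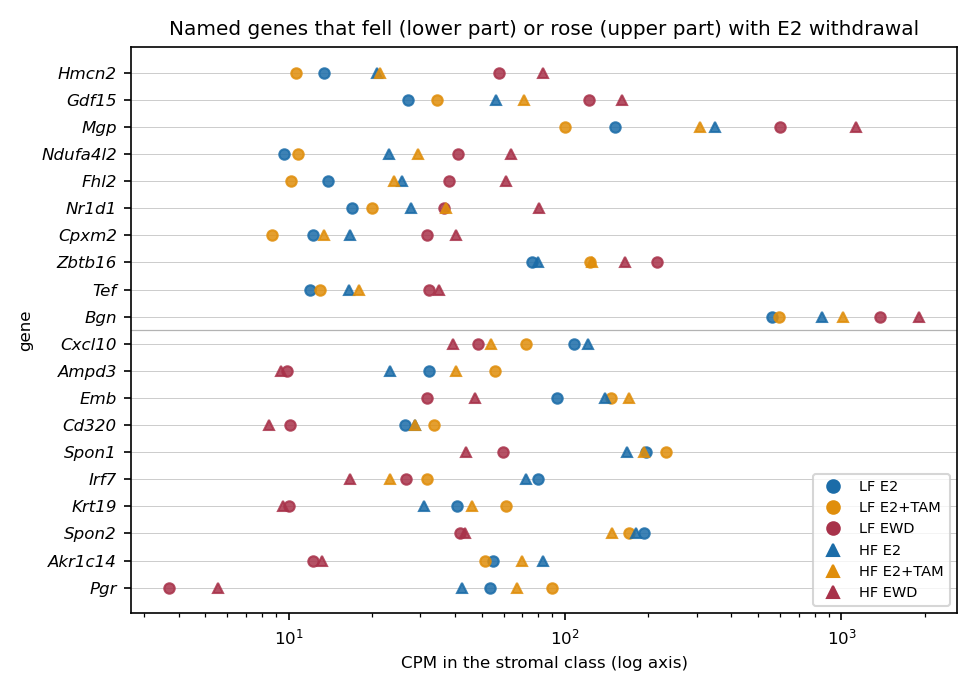
CPM of the named genes that fell (lower part) or rose (upper part) with E2 withdrawal, on a logarithmic horizontal axis, 1 point per library with LF libraries as circles and HF libraries as triangles. Pgr was at 53.7 and 42.5 CPM in the E2 libraries and at 3.70 and 5.54 CPM in the EWD libraries, and Mgp at 151 and 349 CPM against 601 and 1133 CPM.

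Several clock genes rose with withdrawal. In the circadian list 6 of 14 measured members rose, 0 fell and 8 were not called, and 11 were higher when adjusted over the list alone. Those that rose were the repressors Nr1d1 and Nr1d2 (0.93 ± 0.08) and Cry2 (0.89 ± 0.09), the output factor Tef, and Per2 and Per3, which were chosen for naming after their values were seen. The list median was 0.83 (camera adjusted p = 1.36e-20, and adjusted p = 0.256 with an estimated correlation). Several interferon-response genes fell. In this list 4 of 19 fell, 0 rose and 15 were not called, and 13 were lower when adjusted over the list alone. The 4 were Irf7, Rsad2, Oasl2 and Usp18, the last 3 named after their values were seen, while Ifit3 had -2.35 ± 0.29 and Isg15 -1.41 ± 0.25 without a call. The interferon list median was -0.73 (camera adjusted p = 2.29e-27, and adjusted p = 0.394 with an estimated correlation).

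Collagen genes had mostly higher values with withdrawal and no single call. Of 17 measured, 0 passed over all genes (edgeR, while DESeq2 called 1021 genes for the E2 withdrawal effect), 8 were higher when adjusted over the list alone, and the median was 0.44 (camera adjusted p = 5.4e-06, and adjusted p = 0.394 with an estimated correlation), with 0.63 ± 0.11 for Col6a2 and 0.61 ± 0.19 for Col3a1. Among matrix glycoproteins, Bgn rose and Thbs2, a thrombospondin, fell by 0.94 on the log2 scale, with 23 of 25 not called and no call by camera (adjusted p = 0.0612). Of the glucocorticoid-response list Zbtb16 rose and 11 of 12 were not called, with 7 higher when adjusted over the list alone and a median of 0.41 (camera adjusted p = 5.4e-06, and adjusted p = 0.394 with an estimated correlation). Its member Tsc22d3 had 1.62 ± 0.20. In the p53 and senescence list Gdf15 and the stress-response gene Sesn2 (0.78 ± 0.08) rose and 11 of 13 were not called, with 7 higher and 1 lower when adjusted over the list alone (median 0.39, camera adjusted p = 3.81e-04, and adjusted p = 0.394 with an estimated correlation). The cholesterol synthesis list had 0 of 18 called, 3 higher when adjusted over the list alone and a median of 0.55 (camera adjusted p = 1.02e-04, and adjusted p = 0.607 with an estimated correlation), with 0.79 ± 0.23 for Idi1 and 0.78 ± 0.16 for Sqle. From E2 to EWD, its member Hmgcs1 went from 100 to 99.0 CPM on LF and from 102 to 209 CPM on HF. Msmo1 went from 55.7 to 64.2 and from 51.0 to 93.1 CPM, and Cyp51 from 51.9 to 66.0 and from 56.1 to 99.1 CPM. These members were picked for their tamoxifen ratios, and the difference between diets was not tested. The progenitor identity list had 0 of 13 called, 2 lower when adjusted over the list alone and a median of -0.41 (camera adjusted p = 2.6e-04, and adjusted p = 0.607 with an estimated correlation), with -1.36 ± 0.18 for Anxa3. The share of Dpp4 progenitor-like cells was lower in the EWD libraries, and within those cells Dpp4 had -0.035 ± 0.131 (adjusted p = 0.899, edgeR). Within preadipocyte-like cells Dpp4 had -0.54 ± 0.08 (adjusted p = 0.0648, edgeR) and in the Tnc cluster -0.66 ± 0.20 (adjusted p = 0.21), neither called. Its value was not positive in any subtype fitted. Anxa3 was called lower within preadipocyte-like cells (-2.10 ± 0.10, adjusted p = 0.0067, edgeR), the Tnc cluster (-2.57 ± 0.14, adjusted p = 3.95e-04) and F3 stroma-like cells (-1.82 ± 0.12, adjusted p = 0.00308).

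In the estrogen-response list Pgr and Greb1 fell and 14 of 16 were not called. Adjusted over the list alone, 5 were lower and 3 higher, and its median of -0.13 and its mean of -0.37 both lay below 0 (camera adjusted p = 0.032, and adjusted p = 0.394 with an estimated correlation). The heat shock (median 0.29), oxidative stress (0.23), immediate early (-0.25) and ribosomal protein (-0.14) lists were also called by camera, at adjusted p = 3.81e-04, 0.00542, 0.00198 and 0.0168, with 0, 0, 0 and 1 members called. With an estimated correlation their adjusted p were 0.394, 0.394, 0.631 and 0.687. In all, camera with its preset correlation called 13 of 27 lists, and both camera with an estimated correlation and fry called 0, with 0.104 as the lowest adjusted p of fry. The estimated correlation leaves camera little power with so few residual degrees of freedom, so its lack of calls does not decide whether these lists moved. With its preset correlation camera takes its degrees of freedom from the number of genes, not from the libraries. Those p-values, however small, therefore do not measure spread between libraries and do not decide it either. In lists that camera did not call, Ctsk, a collagen-degrading protease (0.81 ± 0.10), rose and Cxcl10 fell.

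**Figure D3:**
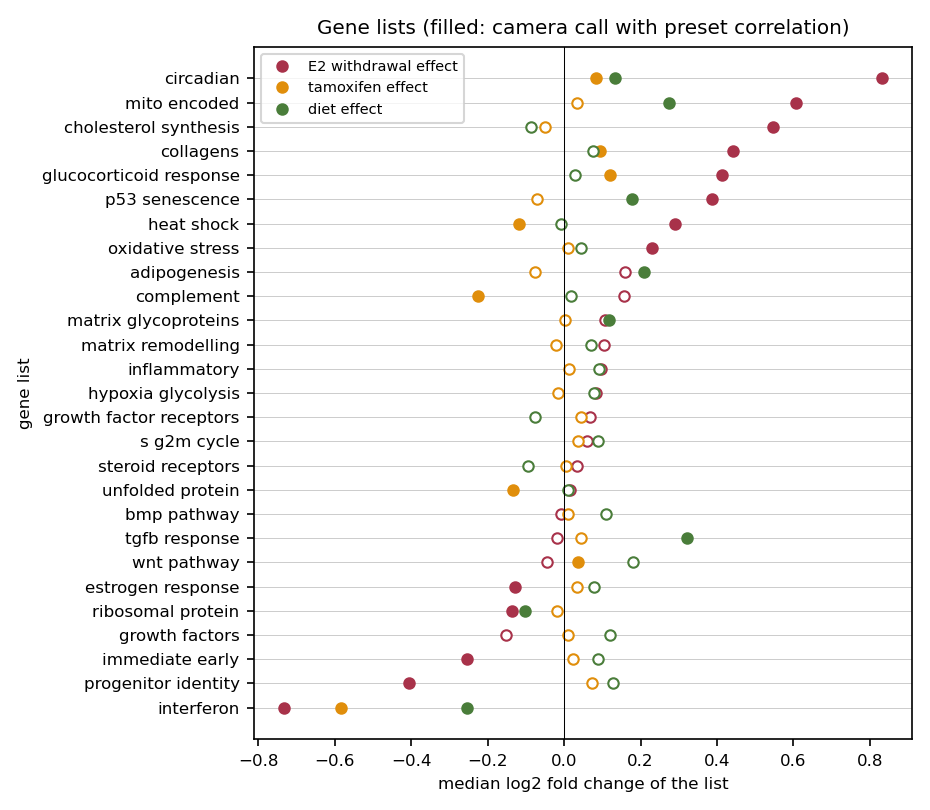
Median log2 fold change of each of the 27 gene lists (horizontal axis) for withdrawal, tamoxifen and diet, with filled points for lists called by camera at its preset correlation of 0.01 and open points for the others. With withdrawal the circadian list lay highest at 0.83 and the interferon list lowest at -0.73, and 0 lists were called with an estimated correlation.

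Measures of RNA quality and cell makeup moved with withdrawal as well. The median mitochondrial share of UMIs per class cell was 0.793% and 0.888% in the LF and HF EWD libraries, against 0.537% and 0.624% with E2 and 0.494% and 0.646% with E2+TAM. The mitochondrially encoded list had 1 of 13 called (mt-Nd4l, 0.83 ± 0.10), 8 higher when adjusted over the list alone and a median of 0.61 (camera adjusted p = 1.04e-12, and adjusted p = 0.394 with an estimated correlation). Marker lists of other cell types had medians of 0.88 for dendritic and 0.87 for neutrophil genes, with 0 called in either. The mural marker Notch3 rose (1.54 ± 0.10) with 7 of 8 mural markers not called, and the mesothelial marker Krt19 fell with 4 of 5 not called. In the first clustering, on all variable genes, cluster 0 held 46.7% and 52.4% of the LF and HF EWD class. It held 14.4% and 13.8% with E2 and 13.2% and 5.52% with E2+TAM. Cluster 1 was the largest with E2 at 20.7% and 17.4%. Cluster 3, with Emb and Gdf15 among its leading genes, fell from 10.5% and 11.5% with E2 to 0.895% and 0.839% with EWD. Cluster 7, with Pgr, Ampd3 and Krt19 among its leading genes, fell from 8.99% and 2.92% to 0.16% and 0.399%. Whether these shares carried the values of the called genes was not tested. A cluster of 376 cells led by interferon genes lay within the class, and without it the interferon list had 2 members called and a median of -0.59. The p-values measure only how far the treatment response of these pooled libraries differed between the diets, with 2 residual degrees of freedom. Every left-out library moved the count of 124 for the E2 withdrawal effect: 57 without LF E2, 35 without HF E2, 241 without LF E2+TAM, 262 without HF E2+TAM, 4352 without LF EWD and 4264 without HF EWD. Without an E2 or an EWD library that arm is a single library, and the spread comes only from the other groups.

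The response was also read within 5 of the 6 subtypes alone, which was added after seeing the data, and the Uts2 cluster of 326 cells was not fitted. Pgr fell in preadipocyte-like cells by 2.74 on the log2 scale (SE 0.27, adjusted p = 0.0221, edgeR), in Dpp4 progenitor-like cells by 3.42 (SE 0.08, adjusted p = 0.000695), in F3 stroma-like cells by 2.41 (SE 0.16, adjusted p = 0.00298) and in the Tnc cluster by 1.30 (SE 0.20, adjusted p = 0.0325). Nr1d1 rose in these subtypes by 1.61 ± 0.14, 1.03 ± 0.09, 1.56 ± 0.15 and 1.66 ± 0.14. Igf1 was called higher in preadipocyte-like cells (1.15 ± 0.10, adjusted p = 0.0145, edgeR), Esr1 in Dpp4 progenitor-like cells (0.69 ± 0.08, adjusted p = 0.0159) and Fabp4 in F3 stroma-like cells (0.60 ± 0.10, adjusted p = 0.0399); differences between subtypes were not tested. The counts of called genes were 132 in preadipocyte-like cells (77 shared with the class), 1024 in Dpp4 progenitor-like cells (81 shared), 128 in the Tnc cluster (29 shared), 187 in F3 stroma-like cells (49 shared) and 9 in the Cilp cluster (5 shared). Of these 5 the Cilp cluster had the fewest cells, 1103.

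Tamoxifen was compared with E2 alone across both diets. The values of interferon-response genes were lower with tamoxifen, led by Ifit3 (-2.17 ± 0.29), an interferon-induced antiviral gene, and Irf7 (-1.49 ± 0.14), but not in the Tnc cluster alone, where Irf7 had 0.022, Ifit3 0.087 and Usp18 0.30. Sfrp1 (-0.75 ± 0.08) and Sfrp2 (-1.15 ± 0.13), secreted modulators of Wnt signalling, Sdc1, a heparan sulfate proteoglycan (-1.07 ± 0.14), and Crispld1 (-0.94 ± 0.08) had lower values too. Higher values were those of Ampd3 (0.79 ± 0.12), Zbtb16 (0.68 ± 0.13), Krt19 (0.59 ± 0.11), Cmklr1, the chemerin receptor (0.52 ± 0.08), and Psen2 (0.49 ± 0.08). None of these was called over all genes in the 6 libraries: edgeR's quasi-likelihood test called 0 of 19426 genes, with 650 at an unadjusted p under 0.05 against 971 by chance, and DESeq2 called 109. The smallest adjusted p was 0.235 (edgeR), for Crispld1 and Irf7 among others. Other named genes with lower values were Ctla2a (-0.62 ± 0.08), Usp18 (-0.75 ± 0.10), Tac1 (-0.74 ± 0.10) and Itm2a (-0.76 ± 0.11), and others with higher values were Ror2 (0.47 ± 0.09), Ncoa7 (0.38 ± 0.08), Inf2 (0.47 ± 0.10), Elmo1 (0.40 ± 0.08) and C1qtnf1 (0.39 ± 0.08). Pgr had 0.70 ± 0.23, Greb1 -0.75 ± 0.21, Esr1 0.05 ± 0.09 and Pparg -0.27 ± 0.17.

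The interferon list had 0 of 19 called with tamoxifen, 14 lower when adjusted over the list alone and a median of -0.58 (camera adjusted p = 7.37e-75, and adjusted p = 0.593 with an estimated correlation). This list was thus lower in both comparisons with E2, which share the E2 libraries, and without the interferon-led cluster its median was -0.52. Camera also called complement genes (median -0.22, adjusted p = 5.67e-04), glucocorticoid-response genes (0.12, 0.00109), unfolded protein response genes (-0.13, 0.00572), circadian genes (0.08, 0.0116), collagens (0.09, 0.0143) and heat shock genes (-0.12, 0.0493), each with 0 members called. With an estimated correlation their adjusted p were 0.593, 0.810, 0.810, 0.593, 0.810 and 0.810. The Wnt pathway list was called lower (adjusted p = 0.00463, and adjusted p = 0.593 with an estimated correlation) with a mean of -0.14 but a median of 0.04. Camera called 8 lists with its preset correlation, and 0 with an estimated correlation or by fry.

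With the EWD libraries left out, an alternative chosen after seeing the data, the E2 and E2+TAM libraries gave 463 tamoxifen calls among 19776 genes (edgeR quasi-likelihood test, 1 residual degree of freedom), of which 112 rose and 351 fell. In this fit Irf7 (-1.48 ± 0.08, adjusted p = 3.5e-05, edgeR), Sfrp2 (-1.15 ± 0.06), Sdc1 (-1.08 ± 0.08), Crispld1 (-0.94 ± 0.06), Postn, the matrix protein periostin (-0.81 ± 0.09), Sfrp1 (-0.75 ± 0.06) and Usp18 (-0.74 ± 0.07) fell. Ampd3 (0.79 ± 0.06), Pgr (0.70 ± 0.06, adjusted p = 1.29e-04, edgeR), Zbtb16 (0.68 ± 0.06), Krt19 (0.58 ± 0.06) and the collagen gene Col1a1 (0.46 ± 0.08) rose. Greb1 (-0.75 ± 0.28) and Ifit3 (-2.13 ± 0.22) were not called. Sdc1 and Postn were among the leading genes of a cluster of the first clustering. It held 6.85% and 7.18% of the class in LF E2 and HF E2, and 1.36% and 0.196% in LF E2+TAM and HF E2+TAM. Its share was also low with withdrawal, at 0.094% in LF EWD and 0.157% in HF EWD. In the interferon list 11 of 19 fell, and all 19 were lower when adjusted over the list alone (camera adjusted p = 1.46e-77, and adjusted p = 0.877 with an estimated correlation). The counts in the 6-library fit with 1 library left out were 433 without LF EWD, 432 without HF EWD, 6 without LF E2, 3 without LF E2+TAM, 1 without HF E2+TAM and 0 without HF E2, the last 4 with 1 arm as a single library and a spread that comes only from the other groups. With 1 EWD library left out, the other was fitted exactly and added nothing to the tamoxifen estimate. The counts of 433 and 432 thus rest on the same 4 libraries as the 463 and are no separate check. The estimates of the full 6-library fit rest on these 4 libraries as well, so their signs could not differ much.

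The contrast of tamoxifen against withdrawal was tested directly, without the E2 libraries as a common control. These libraries still entered the fit and its spread. Pgr was 4.06 ± 0.27 higher on the log2 scale with E2+TAM than with EWD (adjusted p = 0.0118, edgeR), Krt19 2.44 ± 0.12 (adjusted p = 0.00614), Ampd3 2.30 ± 0.13, Akr1c14 2.23 ± 0.14, Greb1 2.16 ± 0.23 and Spon1 2.05 ± 0.10. Mgp (-2.23 ± 0.19), Hmcn2 (-2.19 ± 0.14), Cpxm2 (-1.72 ± 0.11), Gdf15 (-1.51 ± 0.18) and Fhl2 were lower. Of 19426 genes, 150 were called (edgeR quasi-likelihood test, adjusted p under 0.05), 77 higher and 73 lower with E2+TAM. The count was 49 without LF E2+TAM, 4989 without LF EWD and 4343 without HF EWD, each with 1 arm as a single library and a spread that comes only from the other groups.

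The diet effect was tested across the 3 treatments. Values on HF were higher for Prg4, a lubricating proteoglycan (1.25 ± 0.08), Mgp (1.25 ± 0.15), Itgbl1 (0.96 ± 0.11), Nr1d1 (0.92 ± 0.10), Fhl2 (0.93 ± 0.12), Nov, a matricellular protein (0.87 ± 0.10), Arc (0.82 ± 0.07), Ctla2a (0.75 ± 0.07), the elastic fiber gene Fbln5 (0.71 ± 0.07) and the tubulin gene Tuba1c (0.64 ± 0.08). They were lower for Ccl19, a chemokine (-1.01 ± 0.17), Mcoln2 (-0.66 ± 0.07), the fatty acid elongase gene Elovl6 (-0.54 ± 0.09), Tac1 (-0.53 ± 0.08), Arhgap20 (-0.51 ± 0.07), Scg3 (-0.44 ± 0.06), Sfrp1 (-0.43 ± 0.07), Asxl1 (-0.42 ± 0.07) and Srp54a (-0.34 ± 0.06). No gene was called in the 6 libraries: edgeR's quasi-likelihood test called 0 of 19426, with 2175 at an unadjusted p under 0.05 against 971 by chance, and DESeq2 called 262. The smallest adjusted p was 0.256 (edgeR), for Prg4.

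Genes that respond to TGF-beta had mostly higher values on HF, with 0 of 16 called, 4 higher when adjusted over the list alone and a median of 0.32 (camera adjusted p = 5.48e-07, and adjusted p = 0.55 with an estimated correlation). Adipogenesis genes had 0 of 22 called, 3 higher when adjusted over the list alone and a median of 0.21 (camera adjusted p = 0.00348, and adjusted p = 0.609 with an estimated correlation), with 0.58 ± 0.13 for Fabp4 and 0.43 ± 0.14 for Pparg. Matrix glycoproteins had 6 of 25 higher when adjusted over the list alone (median 0.12, camera adjusted p = 0.00125, and adjusted p = 0.544 with an estimated correlation). Camera also called the interferon (median -0.25, adjusted p = 1.61e-06), mitochondrially encoded (0.27, 1.29e-05), circadian (0.13, 2.71e-04), p53 and senescence (0.18, 0.00125) and ribosomal protein (-0.10, 0.00125) lists. With an estimated correlation their adjusted p were 0.609, 0.609, 0.544, 0.544 and 0.672. Camera called 8 lists in all and 0 with an estimated correlation or by fry. Among markers of other cell types, the epithelial list had a median of 1.02 with 4 of 6 higher when adjusted over the list alone, and the endothelial list 0.51 with 3 of 8, none called over all genes.

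In the E2 and E2+TAM libraries alone, again an alternative chosen after seeing the data, 3018 of 19776 genes were called for diet (edgeR quasi-likelihood test, 1 residual degree of freedom), 1490 higher and 1528 lower on HF, of which 1219 changed more than 1.5-fold. Mfap4, a microfibril protein (2.12 ± 0.11), the matrix protease gene Mmp11 (1.58 ± 0.07), Mgp (1.41 ± 0.11) and Prg4 (1.32 ± 0.06) rose on HF, while the matrix lists were mixed, with 7 of 25 matrix glycoproteins rising and 2 falling and 3 of 17 collagens rising and 1 falling. The monocyte chemokine gene Ccl2 (0.80 ± 0.09), the lipid droplet gene Plin2 (0.88 ± 0.08), Fabp4 (0.69 ± 0.10, adjusted p = 0.00500, edgeR) and Pparg (0.63 ± 0.07) also rose. Ccl19 (-0.78 ± 0.10), Pgr (-0.38 ± 0.06, adjusted p = 0.00313, edgeR), Dpp4 (-0.31 ± 0.07) and Esr1 (-0.26 ± 0.06) were called lower. Within Dpp4 progenitor-like cells, whose share was lower in these HF libraries, Dpp4 stood at 529 and 497 CPM in LF E2 and LF E2+TAM and at 543 and 535 CPM in HF E2 and HF E2+TAM. The EWD libraries, left out here, did not all share these directions. From LF EWD to HF EWD, Plin2 stood at 596 and 488 CPM, Pparg at 43.0 and 43.8, Pgr at 3.70 and 5.54, Dpp4 at 116 and 121 and the immediate early gene Zfp36 at 1272 and 916. Over 6 libraries Plin2 had 0.50 ± 0.26, Pgr -0.10 ± 0.20 and Dpp4 -0.18 ± 0.10, none of them called. Mfap4 was a leading gene of both the Uts2 and Cilp clusters. The Uts2 cluster held 0.144% and 0.123% of the class in LF E2 and LF E2+TAM and 0.783% and 1.58% in HF E2 and HF E2+TAM. The Cilp cluster held 1.45% and 1.57% against 2.71% and 1.45% in the same order. A cluster of the first clustering also led by Cilp had a median of 13454 UMI per cell, against 4083 in the Cilp cluster. It held 1.08% and 0.736% against 3.63% and 1.18% in the same order. Whether these shares carried the value of Mfap4 was not tested. By list, 12 of 18 immediate early genes rose and 0 fell, 10 of 22 adipogenesis genes rose and 1 fell, and 9 of 16 TGF-beta response genes rose and 1 fell (camera adjusted p = 2.61e-10, 7.16e-08 and 2.05e-07, each adjusted p = 0.65 with an estimated correlation). Over 6 libraries the immediate early list was not called (median 0.09, camera adjusted p = 0.222). A cluster of the first clustering had Txnip, Fos and Jun among its leading genes. It held 3.30%, 4.21% and 4.71% of the class in LF E2, LF E2+TAM and LF EWD and 9.60%, 16.8% and 0.755% in the HF libraries. Whether it carried the values of the list was not tested. Of the mitochondrially encoded list, a measure of RNA quality, 6 of 13 rose and 0 fell (median 0.33, camera adjusted p = 3.43e-04, and adjusted p = 0.65 with an estimated correlation). In the 6-library fit of the diet effect with 1 library left out the counts were 2781 without LF EWD, 2827 without HF EWD, 2 without LF E2, 2 without HF E2, 0 without LF E2+TAM and 0 without HF E2+TAM. With 1 EWD library left out, the other was fitted exactly and added nothing to the diet estimate. The counts of 2781 and 2827 thus rest on the same libraries as the 3018 and are no separate check. Each diet and treatment was still 1 pool of mice, so a difference between pools enters these counts as a difference of diet.

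Treatment effects were compared between the diets within pairs of libraries, for which no replicate check exists. Withdrawal lowered Spon2 by a log2 ratio of -2.21 on LF and -2.05 on HF, and Spon1 by -1.71 and -1.94. Its ratios for Mgp were 1.99 and 1.70 and for Gdf15 2.17 and 1.52, with Poisson intervals of 1.97 to 2.01 and 1.68 to 1.71 for Mgp. Other large ratios on LF were those of Tmem100 (-2.17), Thbd (-1.75), Tsc22d3 (1.97), Vtn (1.84) and Lrrc32 (1.78), and on HF those of Fos (-1.94), Isg15 (-1.93), Cxcl10 (-1.62), Cxcl2 (1.32) and Smpd3 (1.27). The largest differences between diets were in Smpd3, at -0.45 on LF and 1.27 on HF, Fos, at -0.31 and -1.94, H2-Q4, at 1.63 and 0.02, and Tmem100, at -2.17 and -0.62, and these differences were not tested. H2-Q4 may share reads with other H2-Q genes. For tamoxifen, the ratios of Isg15 were -1.08 on LF and -1.71 on HF, those of Sfrp2 -1.11 and -1.19, and those of Zbtb16 0.70 and 0.66. Iigp1 (-0.92) and Emb (0.65) were among the largest on LF and Plac8 (-1.27) and Cxcl10 (-1.16) among those on HF.

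Across 3308 genes with a mean of at least 50 CPM, the log2 ratios of withdrawal on LF and HF had a Pearson correlation of 0.546 and a Spearman correlation of 0.452, with 65% of genes of the same sign. The corresponding values for tamoxifen were 0.343, 0.249 and 58.5%. Mismatched pairs, which share no library, had Pearson correlations of 0.134 (withdrawal on LF with tamoxifen on HF) and 0.049 (tamoxifen on LF with withdrawal on HF). These 4 correlations are across genes, which are not independent replicates, and carry no p-value. Over all kept cells in place of the stromal class the Pearson correlation for withdrawal was 0.107, the Spearman correlation 0.428 and the share of the same sign 63.6%, while the mismatched pairs had Pearson correlations of -0.378 and 0.119.

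**Figure D4:**
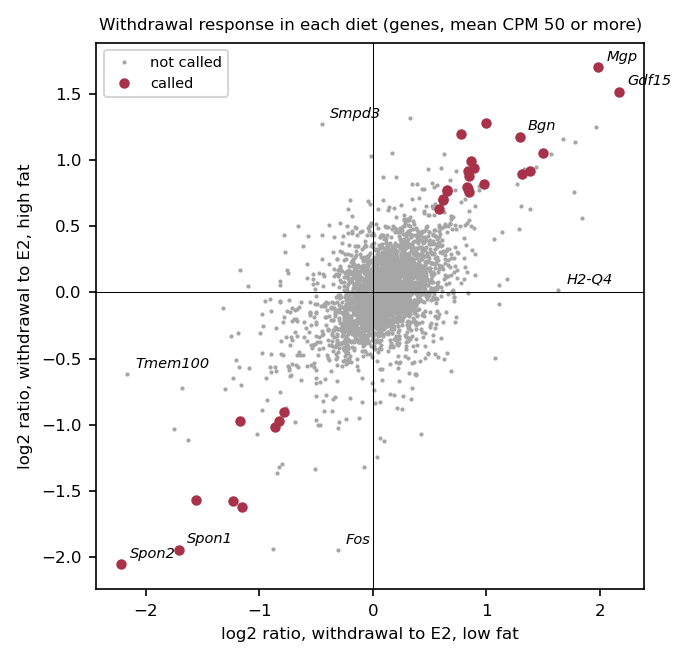
Log2 ratio of EWD to E2 on LF (horizontal axis) and on HF (vertical axis) for 3308 genes with a mean of at least 50 CPM, with genes called for withdrawal in red. The Pearson correlation was 0.546, Mgp lay at 1.99 and 1.70, and Spon2 at -2.21 and -2.05.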

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

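The tests in this part on subtype shares, subtype-specific circadian values, tamoxifen against withdrawal and diet splits were chosen only after the results were seen, and those on mitochondrial share and the interferon-led cluster were set before their outcome was read.

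Several genes had treatment ratios of opposite sign in the diets, each from 2 pairs of single libraries and not tested. The signs were taken with Poisson intervals, which cover counting error only, and some ratios were close to 0. Cebpd had 0.04 on LF and -1.24 on HF with withdrawal, and Gmcl1 -0.10 and 0.80 with tamoxifen. For withdrawal the HF log2 ratio minus the LF log2 ratio was -1.50 for Txnip, an inhibitor of thioredoxin, -1.28 for Cebpd, an early adipogenic transcription factor, 1.72 for Smpd3, a sphingomyelinase, and 1.16 for Gapdh, a glycolytic enzyme. For tamoxifen the differences were -0.90 for Hmgcs1, -0.86 for Cyp51 and -0.70 for Msmo1, enzymes of cholesterol synthesis, and 1.18 for the olfactory receptor gene Olfr1309, 1.07 for Mid1, 1.04 for Kpna6, 1.004 for the polymerase subunit gene Pola2 and 0.91 for Gmcl1. Txnip led a cluster of the first clustering that held 3.30% of the class in LF E2 and 4.71% in LF EWD. That cluster held 9.60% in HF E2 and 0.755% in HF EWD. The differences between diets were not tested, nor was their cause.

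Cells outside the stromal class differed between libraries as well. T cell-like cells made up 0.374% of kept cells in LF EWD (exact Clopper-Pearson 95% interval 0.269 to 0.505) and 0.0843% in LF E2. The immunoglobulin-led cluster held 1.79% in LF EWD against 0.273% in LF E2, and 0.559% in HF EWD against 0.25% in HF E2. Mural-like cells held 1.17% in HF EWD and 0.294% in HF E2. The sort was meant to remove CD45+ cells, so these shares follow both the tissue and the sort, and the differences were not tested.

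The 124 genes called with withdrawal, led by Pgr and Greb1, could come from a shift between stromal subtypes rather than from change within cells. Within preadipocyte-like cells alone, 120 of these genes kept a median of 0.938 of their change in the class (quartiles 0.822 to 1.06). A shift between these subtypes alone would leave little change within preadipocyte-like cells, so it was not the whole cause. The subtypes were formed without 587 genes that differed between libraries, so a shift between states within a subtype cannot be excluded. The medians were 0.800 in Dpp4 progenitor-like cells (lower quartile 0.498), 0.549 in the Tnc cluster (0.295), 0.709 in F3 stroma-like cells (0.465) and 1.03 in the Cilp cluster (0.648). A higher mitochondrial share in the EWD libraries could also raise or lower genes through cell quality. Among cells with shares between 0.5% and 1%, 123 of the genes kept a median of 0.907 (quartiles 0.851 to 0.966). The median share of these cells was still 0.662% and 0.691% in LF E2 and HF E2 against 0.753% and 0.787% in LF EWD and HF EWD. This gap was narrower than in the class while most of the change stayed, which argues against the mitochondrial share as the whole cause. A gap remained, and other aspects of cell quality were not tested.

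Interferon-response genes such as Irf7 and Isg15 were lower with both withdrawal and tamoxifen, which share the E2 libraries, so a difference of those 2 libraries could enter both. Without the interferon-led cluster the list median was -0.59 for withdrawal and -0.52 for tamoxifen, which excludes that cluster as the whole cause. Tamoxifen against withdrawal, in which the E2 libraries are no control but still enter the fit, had a list median of 0.13. Both a response to E2 and a separate handling of the E2 libraries could give that value, so it cannot tell between them.

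Circadian genes such as Nr1d1 and Tef rose with withdrawal, and their levels may follow the hour of tissue collection, which is not given. The lowest list median in the 4 larger subtypes was 0.85, so a shift between these subtypes was not the whole cause. A shift between states within a subtype cannot be excluded. Arntl, which oscillates opposite to Nr1d1, had -0.064, and this cannot tell between collection time and a response to withdrawal. For diet, 10 splits of the libraries into groups of 3 are too few for a share under 0.05. The real split called 0 genes, and the highest count of the other splits was 0.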

How the results depend on the processing

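The removal of cells with the highest doublet scores, equal weight per subtype, the class without its interferon-led cluster, the mitochondrial band, 5 of the 6 subtypes alone and the E2 and E2+TAM libraries alone were chosen only after the results were seen. No paired analysis was possible because each group holds 1 library, and treatments are compared within diets only through the diet term. A correlation shift of 0.1 or a count ratio of 1.5, both limits set by the analyst, counts as a move. Except where a design or set of cells is the change itself, the cause was not tested.

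Genes called for the E2 withdrawal effect (124, including Pgr, Greb1 and Mgp) numbered 1021 with DESeq2, 230 with equal weight per cluster, 52 with equal weight per subtype, 70 in cells of the mitochondrial band, 1024 in Dpp4 progenitor-like cells, 187 in F3 stroma-like cells and 9 in the Cilp cluster. With each library left out in turn the count ranged from 35 to 4352, where without an E2 or EWD library that arm is a single library. It was 165 with RLE, 165 without the filter on low counts, 120 with the stricter cell filter, 179 with thinned counts, 141 over all kept cells, 133 without the highest doublet scores, 95 without the interferon-led cluster and 83 without the diet term. DESeq2 shared 122 of the 124. Without HF E2, 15 named genes lost their call, among them Mgp, Nr1d1, Tef and Bgn, and without LF E2 13 did, among them Gdf15, Mgp, Tef and Bgn. Pgr, Greb1, Akr1c14, Spon1, Spon2, Hmcn2, Irf7 and Krt19 kept theirs with every library left out. Without the interferon-led cluster Cxcl10, Ctsk and mt-Nd4l lost theirs.

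Genes called for the diet effect (0 with edgeR) numbered 262 with DESeq2, 1 over all kept cells, 5 with equal weight per subtype, 4 in the Tnc cluster, 1 in F3 stroma-like cells, 87 in the Cilp cluster and 3018 in the E2 and E2+TAM libraries alone. They ranged from 0 to 2827 with a library left out. Prg4 was the gene called in F3 stroma-like cells. For the tamoxifen effect (0 with edgeR) they numbered 109 with DESeq2, 1 with equal weight per cluster, 1 in preadipocyte-like cells (Sfrp2), 9 in Dpp4 progenitor-like cells (among them Irf7 and Usp18), 4 in the Tnc cluster (among them Crispld1) and 463 in the E2 and E2+TAM libraries alone. They ranged from 0 to 433 with a library left out. For tamoxifen against withdrawal (150) they numbered 1243 with DESeq2, 239 over all kept cells, 255 with thinned counts, 53 with equal weight per subtype, 882 in Dpp4 progenitor-like cells, 44 in the Tnc cluster, 240 in F3 stroma-like cells and 1 in the Cilp cluster. They ranged from 49 to 4989 with a library left out. The cause was not tested for any of these counts. In the E2 and E2+TAM libraries alone the construction removes the EWD libraries, and the spread of the fit fell to a biological coefficient of variation of 6.8%. Leaving out 1 EWD library nearly repeats that fit for diet and tamoxifen, since the other is fitted exactly. The high counts seen then are no separate check.

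Lists called by camera (13 for withdrawal, 8 for diet, 8 for tamoxifen) numbered 0 with an estimated correlation and 0 with fry in each of the 3 comparisons. Camera with an estimated correlation has little power here, so its lack of calls does not decide whether the lists moved. With the preset correlation its p-values rest on the number of genes and do not measure spread between libraries, so those calls do not decide it either. The interferon list had adjusted p = 0.394 for withdrawal with an estimated correlation, and the circadian list 0.256. The Pearson correlation of withdrawal between diets was 0.107 over all kept cells, with a Spearman correlation of 0.428 and 63.6% of genes of the same sign, and ranged from 0.107 to 0.57 over the alternatives, while that of tamoxifen ranged from 0.25 to 0.434. The cause was not tested.

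Stromal class shares moved little. With the stricter cell filter they were 95.3% in LF E2, 95.5% in LF E2+TAM, 95.5% in LF EWD, 93.3% in HF E2, 91.7% in HF E2+TAM and 92.6% in HF EWD. With the first clustering at resolution 1.0 they were 95.5% in LF E2, 96.1% in LF E2+TAM, 94.99% in LF EWD, 93.3% in HF E2 and 91.7% in HF E2+TAM. The preadipocyte-like difference between EWD and E2 on HF was 10.03 percentage points with the second clustering at resolution 0.5 and 9.52 with the first clustering, and the cause was not tested. That on LF ranged from 17.4 to 18.8, and the Dpp4 progenitor-like difference from -17.8 to -17.2 on LF and from -4.55 to -4.14 on HF.

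Signs reversed mostly in genes that were not called, and the cause was not tested for any. The withdrawal value of Fgf1 (-0.15) was 0.57 with equal weight per cluster, 0.63 with equal weight per subtype, 0.69 in Dpp4 progenitor-like cells, 0.21 in F3 stroma-like cells, 1.46 in the Cilp cluster, and 0.18 and 0.33 without LF E2 and LF EWD, within a range of -0.72 to 0.33 with a library left out. That of Fabp4 (0.40) was -0.53 with equal weight per cluster, -0.027 in preadipocyte-like cells and -0.72 in the Tnc cluster, while Pparg (0.61) was -0.064 in the Tnc cluster and Esr1 (0.58) -0.22 in the Cilp cluster. Of the genes called with withdrawal, Thbs2 (-0.94) was 0.016 in the Tnc cluster and 0.028 in F3 stroma-like cells, and Ctsk (0.81) was -0.13 in F3 stroma-like cells and -0.30 in the Cilp cluster.

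For diet, Pgr (-0.10) was 0.073 with equal weight per cluster, 0.14 with equal weight per subtype, 0.37 in preadipocyte-like cells and 0.32 in the Cilp cluster, and ranged from -0.38 to 0.081 with a library left out. Without LF E2 it was 0.047, without LF E2+TAM 0.081, without HF E2 0.048 and without HF E2+TAM 0.069. Greb1 (-0.04) was 0.22 with equal weight per cluster, 0.37 with equal weight per subtype, 0.40 in preadipocyte-like cells, 0.34 in F3 stroma-like cells, 1.17 in the Cilp cluster, 0.015 without the treatment term, and 0.20 and 0.19 without LF E2+TAM and HF E2+TAM, within a range of -0.25 to 0.20 with a library left out. In Dpp4 progenitor-like cells Scg3 (-0.44) was 0.084. In the Cilp cluster Nov (0.87) was -0.45, Sfrp1 (-0.43) 0.33, Esr1 (-0.32) 0.27, Fgf1 (0.54) -0.15 and Igf1 (-0.35) 0.15. The cause was not tested.

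Equal weight per cluster reversed these genes in the tamoxifen effect: Dpp4 to -0.0073, Ctla2a (-0.62) to 0.042, Esr1 (0.05) to -0.13 and Fabp4 to 0.050. Equal weight per subtype gave -0.19 for Esr1, -0.10 for Igf1, -0.041 for Dpp4 and 0.26 for Fabp4. The mitochondrial band gave -0.035 for Igf1. Preadipocyte-like cells gave -0.12 for Igf1 and -0.33 for Dpp4, and Dpp4 progenitor-like cells -0.11 for Esr1 and -0.054 for Dpp4. The Tnc cluster gave 0.022 for Irf7 (-1.49), 0.30 for Usp18 (-0.75), 0.087 for Ifit3 (-2.17), -0.49 for Fgf1, -0.42 for Igf1, -0.050 for Dpp4, 0.15 for Pparg (-0.27) and 0.78 for Fabp4. F3 stroma-like cells gave -0.022 for Krt19 (0.59), -0.11 for Esr1, -0.17 for Dpp4 and 0.13 for Fabp4. The Cilp cluster gave -0.044 for Inf2 (0.47), -0.71 for Esr1, -0.081 for Fgfr1, -0.30 for Igf1, -0.061 for Dpp4 and 0.42 for Fabp4. Without LF E2, Esr1 was -0.053 and Igf1 -0.064, without LF E2+TAM Dpp4 was -0.095, without HF E2 Fgf1 was -0.061 and Fabp4 0.22, and without HF E2+TAM Igf1 was -0.13 and Fabp4 0.038. With a library left out the ranges were -0.053 to 0.16 for Esr1, -0.061 to 0.64 for Fgf1, -0.13 to 0.15 for Igf1, -0.095 to 0.17 for Dpp4 and -0.27 to 0.22 for Fabp4. The cause was not tested.

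Counting each gene once per alternative, the 34 genes named for withdrawal gave 691 values alike, 124 weaker, 19 stronger and 16 of reversed sign. The 28 named for diet gave 602 alike, 104 stronger and 22 reversed, and the 29 named for tamoxifen 635 alike, 81 stronger and 38 reversed.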

Other observations

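The subtype fits and the fit of 4 libraries read in this part were chosen only after the results were seen.

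Gdf15 and Mgp rose with withdrawal within single subtypes. Gdf15 changed by 2.64 ± 0.14 in F3 stroma-like cells (adjusted p = 0.00121, edgeR) and by 1.61 ± 0.13 in preadipocyte-like cells (adjusted p = 0.0140), and Mgp by 2.34 ± 0.19 in preadipocyte-like cells (adjusted p = 0.0140). Differences between subtypes were not tested. With tamoxifen, Irf7 fell in Dpp4 progenitor-like cells (-2.11 ± 0.15, adjusted p = 0.0421, edgeR), the Wnt modulator Sfrp2 fell in preadipocyte-like cells (-1.55 ± 0.09, adjusted p = 0.0412), and Crispld1 fell in the Tnc cluster (-1.33 ± 0.14, adjusted p = 0.0401). In the class these 3 genes had adjusted p between 0.235 and 0.346. Within preadipocyte-like cells, fry called the circadian (adjusted p = 0.0034) and heat shock (adjusted p = 0.0146) lists for withdrawal, with 0 lists called by fry in the class.

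In the 4 libraries without EWD, Cxcl1, Nr1d1 and Gdf15 rose on HF. Of the inflammatory list 8 of 25 rose on HF and 2 fell, among them the neutrophil chemokine gene Cxcl1 (0.59) higher. Of the circadian list 5 of 14 rose, among them Nr1d1 (0.80), and of the p53 and senescence list 6 of 13 rose and 1 fell, among them Gdf15 (1.04 ± 0.06). Of the interferon list 5 of 19 fell. Camera gave adjusted p = 0.00443, 1.38e-04, 3.36e-06 and 0.012 for these lists, and each had adjusted p = 0.65 with an estimated correlation.

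Clusters outside the stromal class were led by Rgs5 and Acta2 (mural-like), Epcam and Krt8 (epithelial-like), Cldn5 and Cdh5 (endothelial-like), and Trbc2 and Cd3g (T cell-like). They held 258, 159, 124 and 91 cells. A mixed cluster of 298 cells expressed both Krt14 and Acta2 and was not named.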
